A study of Mus musculus with 4 samples.

How the data were processed

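Tibial and femur epiphyses of wild-type mice and of mice with floxed Sox9 and an Acan-CreERT2 allele were digested with Liberase, and single cells were captured with Chromium version 3 chemistry and sequenced on a NovaSeq, per the labels' protocols. The labels give 4 samples, 1 for each genotype at postnatal days 13 and 19. The design text of the series names other ages and a further genotype, and the sample labels were followed. The tamoxifen schedule, the floxed exons and the mouse strain are not given in the sources used here.

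The deposited values are raw UMI counts per gene and barcode, which the authors made with Cell Ranger, version 3.1.0 per the file headers, on the mouse build mm10, per the submitters' processing notes. Those notes also name Seurat 3, with no role given. The lowest barcode in the files held 500 UMIs, and any other filter on barcodes by the authors is not given in the sources used here. Of 31053 features, 30934 matched the GENCODE M21 annotation of GRCm38, from which identifiers and coordinates (counted from 1) were taken. Depth was 70507107 to 76080803 UMIs per library.

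Barcodes with 500 or more genes and at most 15% mitochondrial UMIs were kept. Doublets were scored per library by the Scrublet method in scanpy 1.11.5 and removed above its automatic threshold, 148 and 113 barcodes in the controls and 167 and 387 in the mutants at days 13 and 19, which is 2.03%, 1.22%, 1.96% and 3.24% of those scored. Cells of all libraries were scaled to 10000 UMIs, log-transformed and clustered together on 2000 variable genes, 30 principal components and 15 neighbours by the Leiden method at resolution 1.0 (igraph 0.11.9, Python 3.11.15), without batch correction, which gave 29 clusters. No deposited annotation of cells was used. Clusters were named "-like" from marker genes fixed in advance among their 25 leading genes. A cluster led by no class was also called chondrocyte-like when at least 10 chondrocyte markers stood 3-fold or more above blood-like clusters. This second rule was set after the clusters were seen, and it placed clusters 2, 3, 4 and 6 in the class. Clusters of mixed or low-depth profile stayed unnamed, among them cluster 25, which had markers of both osteoblasts and chondrocytes. They held 11.1% and 29.1% of kept control cells and 18.9% and 27.0% of kept mutant cells at days 13 and 19, so shares of classes would differ under other names.

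UMI counts were summed per library over the cells of a class. The main test was the edgeR 4.0.16 quasi-likelihood test (R 4.3.3, limma 3.58.1) with TMM scaling, filterByExpr and Benjamini-Hochberg adjustment at 0.05, on all 4 libraries with additive genotype and age. This leaves 1 residual degree of freedom, so a gene whose genotype effect differs between ages is hard to call. The common dispersion was 0.0184 and the prior degrees of freedom were 10. At a single age there is 1 library per group and no test was made. Log2 ratios of plain CPM are given there with exact Poisson 95% intervals, and a count of 0 was set to a floor of 3 counts per library for a ratio. Shares have exact Clopper-Pearson intervals. The edgeR procedure was tested on simulated data for the mutant and control comparison, with 200 changed genes. At a dispersion of 0.01 it recovered 79% of 2-fold and 95% of 4-fold changes with 0 false calls among 15124 genes, and at 0.05 it recovered 8% and 85% with 0 false calls among 15094. The simulated counts had independent noise and additive effects, without free RNA, shifts in cell make-up or differences between mice. False calls from those sources were therefore not checked.

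Gene lists (24), markers, the main tests and the rule for named genes were fixed before the data were examined. Most alternatives were too, and rules, tests and alternatives chosen later are named as such where they are given. The rule names Sox9, Sox5, Sox6, Sox8 and Acan. It adds the 12 highest and 12 lowest genes by the smaller log2 ratio of both ages, among genes with 50 CPM or more in the higher genotype at both ages, and up to 4 members per list by mean log2 ratio. For age it takes 10 genes each way in the same manner, for ratios that differ between ages 5 each way, and for other cell classes 3 each way. Mitochondrial, ribosomal protein, haemoglobin, sex-linked and unnamed genes were left out of these rankings. Some named genes are not reported here. Other list members appear only to say which members passed, and they, Col10a1, Bglap2 in other cells and the genes named within clusters were chosen after their values were seen. List members count as measured at 10 CPM or more in at least 1 library, and list medians were compared with 10000 random lists of the same size matched on mean expression. Of the 22 names in the cartilage matrix list 20 matched the annotation. The shares of cells with a UMI were computed after thinning each cell to 2000 UMIs. Class comparisons needed 50 cells in each library. The Acan interval in pericyte-like cells came from 10000 resamplings of cells.

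Alternatives were DESeq2 1.42.0, RLE size factors, no low-count filter, the fit without the second factor, all skeletal-lineage cells, clustering per library, minimums of 200 and 1000 genes, mitochondrial limits of 5% and 25%, doublets kept, mean shares per cell, TMM-scaled ratios, other list filters, resolutions of 0.5 and 2.0 and cycling cells left out. Other tools were numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9.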

Results

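Single-cell RNA was sequenced from the epiphyses of the tibia and femur, the ends of the long bones that hold the articular cartilage, the growth plate and marrow. The mice were wild type or carried floxed Sox9 with the tamoxifen-dependent recombinase CreERT2 under Acan, a gene of cartilage cells, and were 13 or 19 days old. Each of the 4 combinations of genotype and age is 1 library, so there are no replicates. Intervals and floors below cover counting error only. The p-values rest on how far genotype effects differ between the ages, and on dispersion shared across genes. They do not measure the spread between mice of a group. The control libraries held 74011576 UMIs in 8053 barcodes at day 13 and 70507107 in 10138 at day 19. The mutant libraries held 75724167 UMIs in 8993 barcodes at day 13 and 76080803 in 12714 at day 19. After filters, 6207 and 7136 control cells and 7282 and 9593 mutant cells remained, with medians of 9649 and 5450 UMIs in controls and 8919 and 5318 in mutants.

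Chondrocyte-like cells were named from cartilage matrix genes and from markers of hypertrophic and superficial articular chondrocytes. These markers include Mmp13 and other members of the cartilage matrix, hypertrophy and superficial-zone lists, so those lists are not independent of the naming. Chondrocyte-like cells made up 69.9% of kept control cells at day 13 (95% exact interval 68.8 to 71.1) and 48.1% of mutant cells (46.9 to 49.2). At day 19 their share was 14.7% in the control (13.9 to 15.6) and 31.8% in the mutant (30.8 to 32.7). Among skeletal-lineage cells alone the shares were 91.1% and 71.2% at day 13 and 83.3% and 77.7% at day 19, so the direction at day 19 depended on the denominator. The difference of -21.9 percentage points at day 13 was -7.81 with a minimum of 200 genes per barcode, -31.7 with 1000, -30.7 with doublets kept and -13.5 with each library clustered apart. B cell-like cells made up 2.69% and 7.90% of kept cells at day 13 and 26.6% and 10.9% at day 19 in control and mutant. Dissection, digestion and the calling of barcodes also set these shares. Most control chondrocyte-like cells lay in cluster 1, led by Frzb and Matn1, cluster 4, led by Pcp4, Sfrp5 and Ucma, and cluster 8, led by Il17b, Ppa1 and Col10a1. Most mutant chondrocyte-like cells lay in cluster 2, led by Myoc, Pi15 and Cxcl1, and cluster 3, led by Cryba2, Mmp13 and Htra1. Cluster 0, led by the superficial-zone genes Prg4 and Cilp, and the cycling cluster 6 held cells of every library. Values given for the class as a whole therefore compare cells from different clusters.

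Sox9, the transcription factor targeted by the deletion, was measured first in every library. In chondrocyte-like cells Sox9 (ENSMUSG00000000567, chromosome 11, 112782224 to 112787760, plus strand, GRCm38) stood at 358 counts per 1000000 (CPM) in the control and 196 in the mutant at day 13, and at 460 and 175 at day 19. Its log2 ratio of mutant to control was -0.87 at day 13 (95% counting interval -0.91 to -0.83) and -1.39 at day 19 (-1.44 to -1.35), which is 1.83-fold and 2.63-fold lower. The edgeR fit over both ages gave -1.32 ± 0.144 (SE, n = 4 libraries, adjusted p = 6.02e-05). With each cell thinned to 2000 UMIs, a Sox9 UMI was found in 44.8% and 31.8% of chondrocyte-like cells at day 13 and in 53.5% and 28.2% at day 19, control and mutant. In neutrophil-like cells, which should lack Sox9, the shares were 4.65% and 5.64% at day 13 and 2.67% and 2.24% at day 19. Unthinned, the chondrocyte-like shares were 85.2%, 74.4%, 93.4% and 68.6% in control and mutant at day 13 and control and mutant at day 19, at median depths of 11644, 10632, 16219 and 9485 UMIs. The neutrophil-like medians were 3953, 3635, 5402 and 3518 UMIs in the same order. Thinning left out 115, 139, 20 and 124 chondrocyte-like cells that held too few UMIs. The labels do not say which exons were floxed, and 3′ tags may lie outside the deleted part, so the Sox9 level checks neither the labels nor the extent of deletion.

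Among the other SOX factors, Sox5 and Sox8 fell and Sox4 rose. Sox8 (ENSMUSG00000024176, chromosome 17, 25565892 to 25570686) was at 32.5 and 9.94 CPM at day 13 and 24.2 and 11.5 at day 19 in control and mutant, and the edgeR fit gave an adjusted p of 1.00e-04. Sox5 (chromosome 6, 143828425 to 144781977), a partner of Sox9 in cartilage, had log2 ratios of -0.33 and -0.56 at days 13 and 19, with an edgeR adjusted p of 0.00302. Sox4 was 4.35-fold and 2.37-fold higher. The values for Sox6 (chromosome 7, 115470872 to 116038796) were log2 0.70 and 0.30, and it did not pass (edgeR adjusted p = 0.0909). Of the 6 listed SOX factors, 1 rose, 3 fell and 2 did not pass, and 2 rose and 3 fell when adjusted over the list alone.

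The comparison of Sox9 mutant and control chondrocyte-like cells asks which genes differ in these cells when Sox9 is targeted. Acan, the main cartilage proteoglycan (ENSMUSG00000030607, chromosome 7, 79053483 to 79115099), fell from 4369 to 1032 CPM at day 13 and from 4385 to 1249 CPM at day 19, 4.24-fold and 3.51-fold lower, with an edgeR log2 change of -2.13 ± 0.193 (SE, adjusted p = 1.59e-05). Mmp13, a collagenase that cleaves collagen II (ENSMUSG00000050578, chromosome 9, 7272514 to 7283331), rose from 7.15 to 867 CPM at day 13 and from 4.17 to 654 CPM at day 19, 121-fold and 157-fold higher. Across the alternatives its log2 ratio ranged from 4.62 to 7.82 at day 13 and from 4.65 to 7.50 at day 19, lowest with a minimum of 1000 genes per barcode. Postn, which encodes the matrix protein periostin (chromosome 3, 54361109 to 54391037), was 53.4-fold and 33.4-fold higher (log2 from 3.15 to 5.81 and from 2.59 to 7.33 across the alternatives). Prelp, a small leucine-rich proteoglycan gene (chromosome 1, 133910304 to 133921414), was 9.20-fold and 7.99-fold lower. The edgeR fit called 3983 of 15196 tested genes, 2125 higher and 1858 lower in mutants.

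Of the 12 genes that rose the most by the rule, Slurp1 was 107-fold and 111-fold higher at days 13 and 19, Cryba2 97.3-fold and 40.0-fold, and Tnn, which encodes the extracellular matrix protein tenascin-N, 79.8-fold and 28.6-fold. Pi15 was 65.0-fold and 25.7-fold higher, Myoc 37.3-fold and 28.5-fold, and Prrx2, a homeobox gene of limb mesenchyme, 35.2-fold and 10.8-fold. Olfml2b was 20.5-fold and 12.2-fold higher, Ly6c1 19.4-fold and 11.5-fold, the fatty acid binding protein gene Fabp4 13.7-fold and 16.2-fold, and the interferon-induced Ifitm3 10.2-fold and 8.94-fold. Across the alternatives the log2 ratio of Cryba2 ranged from 3.49 to 9.87 at day 13 and from 3.26 to 6.71 at day 19. The lowest values at days 13 and 19 were 5.15 and 3.41 for Pi15, 4.55 and 3.51 for Myoc and 3.97 and 2.78 for Prrx2. In all skeletal-lineage cells the ratios were lower for Ifitm3 (log2 1.40 and 0.94) and Ly6c1 (2.36 and 1.48). Mmp13, Cryba2, Olfml2b, Myoc and Pi15 are leading genes of clusters 2 and 3, which hold most mutant and few control cells.

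Of the 12 genes that fell the most, the cytokine gene Il17b (chromosome 18, 61684887 to 61692538) was 46.3-fold and 186-fold lower in mutants at days 13 and 19. C1qtnf3 was 10.6-fold and 12.6-fold lower, Fam89a 11.1-fold and 6.73-fold, the pyrophosphatase gene Ppa1 7.75-fold and 8.08-fold, and Fxyd2 6.83-fold and 12.1-fold. The carbonic anhydrase gene Car12 was 8.07-fold and 6.68-fold lower, Tnni2 8.14-fold and 5.26-fold, Rflna 6.47-fold and 4.91-fold, and Ncmap 6.57-fold and 4.07-fold. Matn3, a cartilage matrilin, was 6.56-fold and 4.36-fold lower, and the chondroitin sulfotransferase gene Chst11 5.17-fold and 4.27-fold. Il17b, Ppa1, Fxyd2, C1qtnf3 and Car12 are leading genes of cluster 8, Tnni2 of clusters 1 and 4 and Rflna of cluster 4, and these clusters hold more control than mutant cells over both ages together. All 24 genes named by this rule passed the edgeR test, but they were chosen by their ratios in these same libraries, so this is not separate evidence. Across the 7659 measured genes the ratios at both ages correlated with r = 0.87, across genes that are not independent replicates, and 494 genes were at least 2-fold higher and 173 at least 2-fold lower at both ages. The median of all measured genes was 0.20 at day 13 and 0.05 at day 19 on plain CPM, and TMM scaling moved it by -0.26 and -0.12 (log2), so plain ratios lie above the edgeR changes by about that much. DESeq2 called 2361 genes, of which edgeR also called 2353.

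**Figure D1:**
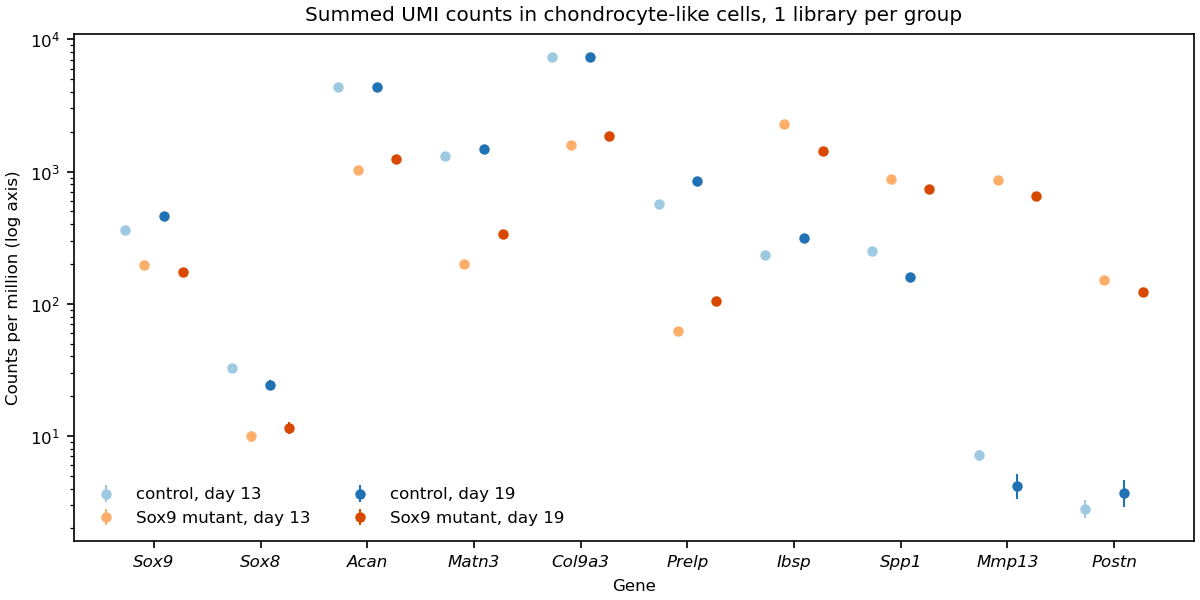
CPM on a log axis in chondrocyte-like cells of the 4 libraries for key genes, with bars for 95% exact counting intervals and 1 library per group. Sox9 lies at 358 and 460 CPM in the controls and at 196 and 175 in the mutants, and Mmp13 at 7.15 and 4.17 against 867 and 654.

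**Figure D2:**
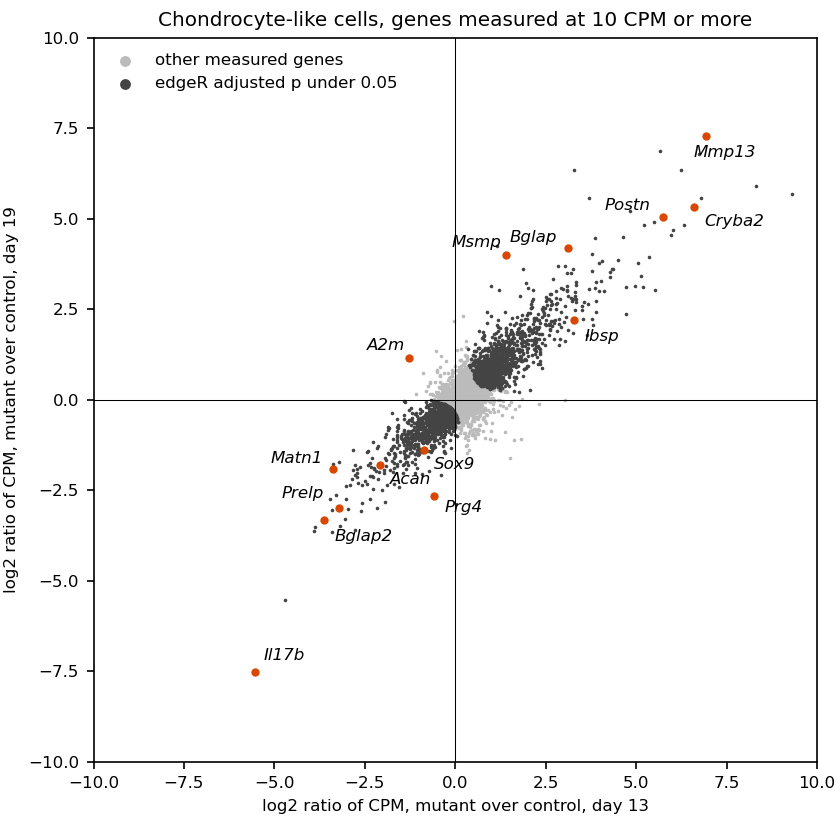
Each point is 1 of 7659 measured genes, with the log2 ratio of mutant to control CPM at day 13 on the x axis and at day 19 on the y axis, in chondrocyte-like cells. Both ratios are positive for Mmp13 (6.92 and 7.29) and negative for Il17b (-5.53 and -7.54) and Acan (-2.08 and -1.81).

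Cartilage matrix genes fell together. Of the 20 tested, 17 fell, 1 rose and 2 did not pass, and adjusted over the list alone 17 fell and 1 rose. Their median log2 ratio was -1.48 at day 13 and -1.23 at day 19, below every one of 10000 random lists matched on expression. Matn1 fell 10.4-fold and 3.76-fold, Col9a3 4.61-fold and 3.93-fold, and Matn3 and Prelp as given above. Chad, which encodes a collagen-binding cartilage protein, rose, and Comp and Fmod did not pass. Members of this list also fell in neutrophil-like (15 of 20, medians -1.51 and -1.59), B cell-like (14 of 20, -1.64 and -0.63) and erythroid-like cells (13 of 20, -1.40 and 0.01). Of 11 enzymes and transporters of sulfate and glycosaminoglycan synthesis, 9 fell, 1 rose and 1 did not pass, the same counts as when adjusted over the list alone, with medians of -0.85 and -1.01. Papss2, which makes the sulfate donor, was 3.03-fold and 3.56-fold lower, the sulfate transporter gene Slc26a2 3.04-fold and 2.52-fold, and Ugdh 2.40-fold and 2.08-fold.

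Genes of fibrous matrix rose together. All 16 of the fibroblast matrix list rose, also when adjusted over the list alone, with medians of 1.60 and 1.76 at days 13 and 19, above every random list. Members of this list also rose in neutrophil-like (11 of 13, medians 2.07 and 2.15), erythroid-like (12 of 13) and B cell-like cells (12 of 13). Tnc was 12.9-fold and 8.31-fold higher, Eln 7.14-fold and 13.1-fold, and Col5a1 6.85-fold and 6.27-fold. Of 13 matrix proteases and inhibitors 11 rose, 1 fell and 1 did not pass, also when adjusted over the list alone, with medians of 1.56 and 1.55. The aggrecanase gene Adamts4 was 16.4-fold and 9.74-fold higher, the stromelysin gene Mmp3 12.5-fold and 3.43-fold, and the serine protease gene Htra1 5.73-fold and 4.60-fold, while Ctsk fell. Members of the protease list also rose in erythroid-like (6 of 7), neutrophil-like (4 of 8) and B cell-like cells (5 of 9).

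Genes of hypertrophic chondrocytes did not move as 1 group over the whole class. Of 12 tested, 5 rose (Mmp13, Ibsp, Spp1, Vegfa and Alpl), 4 fell (Col10a1, Ihh, Panx3 and Runx3) and 3 did not pass, and 6 rose and 5 fell when adjusted over the list alone. The list medians were 0.29 and 0.17, at the 89.1 and 91.9 percentiles of random lists. They ranged from -0.03 to 0.82 and from -0.05 to 0.58 across the alternatives. Ibsp, which encodes bone sialoprotein (chromosome 5, 104299171 to 104311469), was 9.81-fold and 4.62-fold higher, and Spp1, osteopontin, 3.50-fold and 4.63-fold. The channel gene Panx3 was 4.79-fold and 3.75-fold lower. Of 12 osteoblast genes 6 rose (Bglap, Col1a1, Col1a2, Ibsp, Alpl and Spp1), 2 fell (Bglap2 and Smpd3) and 4 did not pass (Runx2, Sp7, Sparc and Dlx5). Ibsp, Alpl and Spp1 are also counted in the hypertrophy list and Col1a1 and Col1a2 in the fibroblast matrix list. The counts of these lists are therefore not independent. When adjusted over the osteoblast list alone 7 rose and 3 fell, and the list medians were 1.06 and 1.16. Across the alternatives these medians ranged from 0.80 to 2.73 and from 0.15 to 2.29. In clusters 0, 1, 4, 6 and 8, respectively, 3, 1, 5, 8 and 11 osteoblast genes rose and 1, 4, 0, 0 and 1 fell. In cluster 25, 2 rose and 7 fell. Members of this list also rose in erythroid-like (6 of 8), neutrophil-like (5 of 9) and B cell-like cells (5 of 10). Bglap, which encodes osteocalcin (chromosome 3, 88383501 to 88384464), was at 39.0 and 340 CPM at day 13 and 24.6 and 448 at day 19 in control and mutant. Its near-identical neighbour Bglap2 (chromosome 3, 88377736 to 88378699) went the other way, from 25.3 to 2.05 CPM and from 17.5 to 1.75, and since reads can be shared between the copies and the strain is not given, both levels are uncertain. Neutrophil-like cells differed in the same direction, with Mmp13 at 4.58 and 84.3 CPM at day 13 and at 0 and 41.7 at day 19 in control and mutant. Thinned to 2000 UMIs, an Ibsp UMI was found in 48.2% and 30.7% of mutant chondrocyte-like cells at days 13 and 19 and in 52.3% and 21.1% of mutant neutrophil-like cells, so the share at day 13 was no higher than in neutrophil-like cells, although its level of 2298 CPM lay above the 357 CPM of those neutrophil-like cells.

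The superficial-zone and resting-zone lists both held genes that rose and genes that fell. Of 10 superficial-zone genes 5 rose, 1 fell and 4 did not pass, the same counts as when adjusted over the list alone, with medians of 1.45 and 0.30, at the 100 and 91.2 percentiles of random lists. In all skeletal-lineage cells the medians were 0.85 and -0.10, and in the superficial cluster 0 itself 0 of 11 rose and 1 fell. Abi3bp was 3.37-fold and 2.64-fold higher, Clu 3.20-fold and 2.08-fold and Tppp3 3.18-fold and 2.21-fold. Prg4, which encodes the joint lubricant lubricin, fell from 695 to 460 CPM at day 13 and from 2144 to 342 at day 19. Of 7 resting-zone genes 4 fell, 1 rose and 2 did not pass, and 4 fell and 2 rose when adjusted over the list alone, with medians of -1.07 and -0.56. Ucma was 5.13-fold and 3.37-fold lower, Sfrp5 4.81-fold and 2.26-fold and Foxa2 2.10-fold and 1.82-fold, while Gas1 rose. Of 20 cell cycle genes only Mcm6 fell and 19 did not pass, also when adjusted over the list alone. The cell cycle median was 0.47 at day 13, with 19 of 20 members higher in the mutant, and -0.63 at day 19, with 0 of 20 higher. In all skeletal-lineage cells it was 0.08 and -0.83. The median ratio of day 19 to day 13 was 0.90 in controls and -0.19 in mutants, and the cycling cluster 6 held 215 of 4341 and 116 of 1051 control and 219 of 3501 and 153 of 3047 mutant chondrocyte-like cells.

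Signalling lists split. Of 5 FGF pathway genes Fgfr2 (4.44-fold and 3.72-fold higher) and Spry2 rose, Fgfr3, a receptor of growth plate chondrocytes, fell (2.59-fold and 1.98-fold lower) and 2 did not pass, also when adjusted over the list alone, with medians of 0.26 and 0.43. Of 10 Wnt pathway genes 2 rose and 4 fell, and 3 rose and 4 fell when adjusted over the list alone. Dkk3 was 6.08-fold and 3.47-fold higher, Ccnd1, cyclin D1, 3.88-fold and 3.82-fold lower, Wnt5b 3.77-fold and 3.15-fold lower and Sfrp1 2.65-fold and 1.79-fold lower. Of 15 BMP and TGF-beta response genes 4 rose, 3 fell and 8 did not pass, and 6 rose and 3 fell when adjusted over the list alone, with medians of 0.27 and 0.18. Bmp7 was 4.70-fold and 3.69-fold lower and Nog, which encodes the BMP antagonist noggin, 2.05-fold and 2.88-fold lower. Of 7 hedgehog and PTHrP signalling genes 2 fell, Hhip and Ihh, and 5 did not pass, and 2 rose and 3 fell when adjusted over the list alone. The medians of the Wnt list (0.15 and -0.09) and the hedgehog list (0.02 and -0.04) were negative at both ages under TMM scaling, at day 13 -0.10 and -0.23. With members at 50 CPM or more alone, the Wnt median at day 13 was -1.41.

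The metabolic and stress lists held genes that rose and genes that fell. Of 18 glycolysis and hypoxia genes 4 rose and 2 fell, also when adjusted over the list alone. Ankrd37 was 5.58-fold and 4.28-fold higher, the hexokinase gene Hk2 2.66-fold and 2.08-fold, Egln3 2.06-fold and 2.58-fold and Vegfa 1.73-fold and 1.84-fold. Of 17 genes of folding and secretion in the endoplasmic reticulum 2 rose and 3 fell, and 2 rose and 4 fell when adjusted over the list alone. Creb3l1 was 3.58-fold and 3.12-fold higher, Ddit3 rose and Creb3l2 fell. Of 7 p53 response genes Phlda3 rose and Ccng1 and Mdm2 fell, also when adjusted over the list alone. Of 3 interferon response genes Ifi27 rose and Bst2 fell, and 2 rose and 1 fell when adjusted over the list alone, with medians of 0.55 and 0.38, which were -0.12 and -0.02 in all skeletal-lineage cells. The medians at day 13 of the glycolysis (0.13), endoplasmic reticulum (0.15) and p53 (0.14) lists turned to -0.13, -0.10 and -0.12 under TMM scaling, and at day 19 they were -0.06, -0.09 and -0.02. Of 16 dissociation stress genes 9 rose, 3 fell and 4 did not pass, and 10 rose and 3 fell when adjusted over the list alone, with medians of 0.75 and 0.63. Ier3 was 2.85-fold and 2.56-fold higher, Dusp1 2.98-fold and 2.21-fold, Hspa1b 2.65-fold and 3.94-fold and Nr4a1 2.51-fold and 2.20-fold.

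Genes of other cell types moved with genotype in the chondrocyte-like cells. All 4 haemoglobin genes fell, with medians of -0.998 and -1.38, and Hbb-bs was at 1022 and 394 CPM at day 13 and at 4327 and 1640 at day 19 in control and mutant. All 6 genes of the neutrophil list rose, with medians of 1.29 and 1.38, led by Lcn2 (15.6-fold and 13.8-fold higher). The neutrophil median at day 19 turned to -0.14 with a minimum of 200 genes per barcode, to -0.28 with each library clustered apart and to -0.37 when clustered without listed genes. Of 2 macrophage genes Cd74 fell and Lyz2 did not pass. Of 2 osteoclast genes Mmp9 rose and Ctsk fell, and the 1 endothelial gene measured, Pecam1, rose. Adjusted over each list alone, the haemoglobin, neutrophil, macrophage, osteoclast and endothelial calls did not change.

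**Figure D3:**
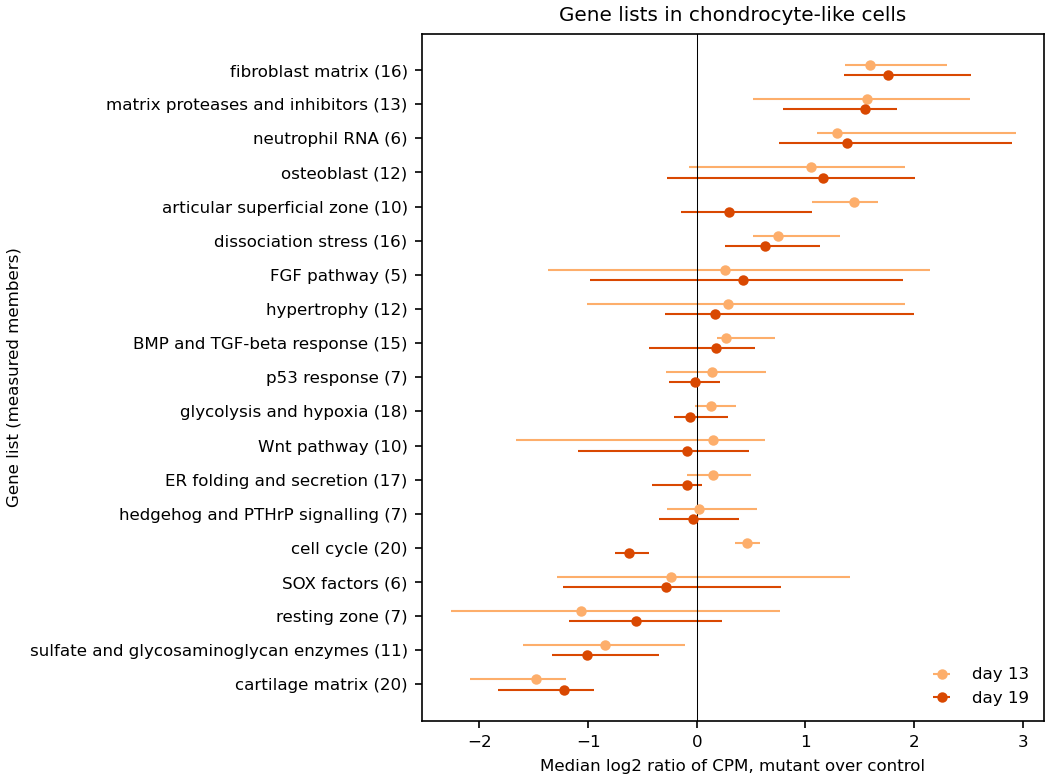
Median log2 ratio of mutant to control CPM in chondrocyte-like cells for the fixed gene lists at day 13 and day 19. Bars are 95% bootstrap intervals over list members. The haemoglobin, interferon, macrophage, osteoclast and endothelial lists, which have few measured members, are not drawn. The fibroblast matrix medians lie at 1.60 and 1.76 and the cartilage matrix medians at -1.48 and -1.23, while the cell cycle list lies on opposite sides of 0 at the 2 ages.

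Within clusters that hold both genotypes, Sox9 and Acan were lower in the mutants in each of the 5 chondrocyte-like clusters with 50 or more cells of every library. In the superficial cluster 0, Sox9 had log2 ratios of -0.35 and -1.11 at days 13 and 19 and an edgeR change of -0.76 (adjusted p = 0.00559), and Acan had an edgeR change of -1.26 (adjusted p = 2.34e-04). In the cycling cluster 6, Sox9 changed by -1.91 (edgeR adjusted p = 9.45e-13) and Acan by -2.21 (3.97e-11). In cluster 1 the edgeR change of Sox9 was -0.88 (adjusted p = 2.35e-05), in cluster 4 it was -1.28 (0.0275) and in cluster 8 it was -1.05 (6.78e-05). Both genes also fell in the unnamed cluster 25 (edgeR adjusted p = 1.52e-05 for Sox9), and neither passed in fibroblast- or tendon-like cells (edgeR adjusted p = 0.718 and 0.407). Sox9 also passed in monocyte- or macrophage-like cells, with log2 ratios of -1.73 and -2.03. Its counts there were 64 and 14 at day 13 and 22 and 10 at day 19 in control and mutant. It did not pass in neutrophil-, B cell- or erythroid-like cells, while Acan passed in each of these classes and in monocyte- or macrophage-like cells. In clusters 0, 1, 4, 6 and 8, respectively, 15, 3, 2, 17 and 14 of the 20 cartilage matrix genes fell, and in neutrophil-like cells 15 of 20 (medians -1.51 and -1.59). Of the fibroblast matrix genes, 8 of 16 rose in cluster 0, 7 of 16 in cluster 1, 10 of 15 in cluster 4, 16 of 16 in cluster 6 and 12 of 16 in cluster 8. Of the hypertrophy genes, 9 of 12 rose and 0 fell in cluster 8, which Col10a1 and Ihh lead, with medians of 1.60 and 1.55. In clusters 0, 1, 4 and 6, respectively, 4 of 10, 1 of 11, 5 of 11 and 7 of 12 rose and 0, 5, 0 and 2 fell, and in neutrophil-like cells 5 of 11 rose and 0 fell. In mutant cells of cluster 6, Mmp13 stood at 522 and 268 CPM at days 13 and 19. In mutant cells of cluster 1 it stood at 35.8 and 19.1 CPM, below the 84.3 and 41.7 CPM of mutant neutrophil-like cells.

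Osteoblast-like cells, led by Ifitm5, Dmp1, Bglap and Ibsp, were 29 cells in the control and 782 in the mutant at day 13, and 16 and 446 at day 19. They made up 0.467% (95% exact interval 0.313 to 0.670) and 10.7% (10.04 to 11.5) of kept cells at day 13, and 0.224% (0.128 to 0.364) and 4.65% (4.24 to 5.09) at day 19. Of skeletal-lineage cells they were 0.608% and 15.9% at day 13 and 1.27% and 11.4% at day 19. When the cells were clustered without any gene of the marker or gene lists, the shares of kept cells were 0.870% and 12.3% at day 13 and 0.266% and 5.31% at day 19. The resulting clusters were still named from the marker genes, so these shares are not independent of those genes. With a minimum of 200 genes per barcode, the difference between mutant and control was 1.88 and 1.60 percentage points, against 10.3 and 4.42 at the minimum used here.

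The comparison of day 19 with day 13 asks what changed with age in the same cell class. Cilp, which encodes a cartilage intermediate layer protein (chromosome 9, 65265180 to 65280605), rose from 8.25 to 73.8 CPM in controls and from 24.2 to 70.9 in mutants, with an edgeR change of 2.28 ± 0.270 (SE, n = 4 libraries, adjusted p = 0.00357). Cytl1 rose from 53.9 to 145 CPM and from 28.2 to 72.8 (edgeR adjusted p = 3.96e-04). Msmp (chromosome 4, 43583216 to 43584494) fell from 230 to 15.2 CPM in controls and from 608 to 244 in mutants (edgeR adjusted p = 0.0385). The imprinted growth genes Dlk1 and Igf2 fell as well, Dlk1 from 549 to 159 CPM in controls and from 512 to 264 in mutants, and Igf2 from 78.2 to 28.4 and from 79.8 to 50.5. The edgeR fit called 109 genes, 94 higher and 15 lower at day 19, and those higher include genes of blood cells, given below. Cilp, Cytl1 and Msmp are leading genes of cluster 0, which held 472 of 4341 and 213 of 1051 control and 562 of 3501 and 385 of 3047 mutant chondrocyte-like cells at days 13 and 19. Its share thus went up in controls and down in mutants, while each of these 3 genes changed in 1 direction in both.

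Of the 10 genes named as higher at day 19, which were chosen by their ratios in these same libraries, 9 passed. The metallothionein genes Mt1 and Mt2 rose by 0.98 ± 0.141 and 1.04 ± 0.142 (edgeR log2) and Crip1 by 1.13 ± 0.139. Hilpda, F3, which encodes tissue factor, and Gsn rose by 0.81, 0.72 and 0.74. Anxa8 did not pass (edgeR adjusted p = 0.0515). Among those named as lower, Msmp, Dlk1 and Igf2 fell. Col1a1 was at 2154 and 1041 CPM in controls and 6100 and 3638 in mutants at days 13 and 19 and did not pass (edgeR adjusted p = 0.0523). Mfap2, Nrep, Slc8a3, Phpt1 and Id3 did not pass either, with log2 ratios of -0.60, -0.50, -0.57, -0.60 and -0.52 in controls and -0.54, -0.63, -0.49, -0.47 and -0.45 in mutants.

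Few members of the fixed lists changed with age. In the superficial-zone list Cilp and Cd44 rose, in the glycolysis list Ankrd37, and Mmp9 fell in the lists of proteases and osteoclast RNA. All 4 haemoglobin, all 6 neutrophil and both macrophage genes rose with age, the haemoglobin genes with medians of 2.32 in controls and 1.99 in mutants and the neutrophil genes with 1.78 and 1.70. Neutrophil-like cells also rose, from 92 of 6207 to 351 of 7136 kept control cells and from 203 of 7282 to 768 of 9593 mutant cells. The erythroid-like cluster 7 rose from 149 to 845 control and from 100 to 653 mutant cells. The rise of haemoglobin and neutrophil genes is thus not separated from the blood content of the libraries. Most other lists had no gene that passed the edgeR test for age. Without genotype in the edgeR fit, 0 genes passed for age and 250 had an unadjusted p under 0.05, and DESeq2 with genotype called 93. The count ranged from 0 to 389 across the settings tried.

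The ratio of mutant to control differed between ages for some genes, which no test could address with 1 library per group. Prg4 had a log2 ratio of -0.60 at day 13 and -2.65 at day 19, Spata7 3.04 and 0.00, Mmp3 3.65 and 1.78, Il17b -5.53 and -7.54, and the growth factor gene Igf1 4.97 and 3.13. Msmp had ratios of 1.40 and 4.002, A2m -1.29 and 1.15, Acta2, the smooth muscle actin gene, -0.04 and 2.17, Matn1 -3.38 and -1.91, and Lars2 0.29 and 1.62.

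The same genotype comparison was made in other cell classes, among them blood cells, which do not make cartilage matrix, to show what differed between these libraries outside the targeted cells. In neutrophil-like cells edgeR called 366 of 7056 genes. Stfa1, a stefin A gene, fell from 8684 to 140 CPM at day 13 and from 1454 to 6.61 at day 19, and Col1a1 rose from 261 to 1526 and from 40.8 to 577. In B cell-like cells edgeR called 264 of 9908 genes. Apobec3, a cytidine deaminase gene of antiviral defence, fell from 264 to 17.5 CPM and from 231 to 16.4, Snhg12 and Iglc2 fell, and Mmp13, Lum and Spp1 rose. In erythroid-like cells 454 of 7539 genes were called by edgeR. Apobec3 fell there with log2 ratios of -3.50 and -4.13, as did Cdca3 and Tspo2, and Ibsp, Lum and Spp1 rose. In monocyte- or macrophage-like cells edgeR called 148 of 7877 genes, with Ibsp, Lepr and Mmp13 rising and Ucma, Acan and Matn3 falling. In control fibroblast- or tendon-like cells Acan stood at 683 and 270 CPM and Sox9 at 121 and 92.3 CPM at days 13 and 19. In control neutrophil-like cells these were 240 and 273 CPM and 13.7 and 30.25 CPM. Fibroblast- or tendon-like cells may thus be among the targeted cells, and edgeR called 53 of 8529 genes in them. Klk1, a kallikrein gene, had 0 counts in both controls and stood at 401 and 176 CPM in the mutants, at least 8.11 and 5.58 higher on the log2 scale against a floor of 3 counts per library, Ibsp and Aqp5 rose, and Col9a3, Col9a2 and Cenpf fell. Skeletal transcripts such as Col1a1, Mmp13 and Acan thus differed between genotypes in blood-like cells too. The strain and litters of the mice are not given, so changes such as those of Apobec3, Stfa1 and Klk1 are not separated from differences between the mice other than Sox9.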

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

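The tests of free RNA and of doublets in neutrophil-like cells and both tests of the Acan level were chosen after those results were seen, and the tests of genes shifted alike across cell classes before.

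The cell cycle list had a median log2 ratio of mutant to control of 0.47 at day 13 and -0.63 at day 19, a difference of -1.09 that was singled out because the ratios had opposite signs at the 2 ages, and which was not tested. In the same way, and also untested, the ratio at day 19 minus that at day 13 was 2.43 for A2m, -1.31 for Rrm2, -0.75 for Cenpa and -1.44 for Ccna2. Within clusters 0, 1, 4, 6 and 8, respectively, the cell cycle medians were 0.10, 0.93, 0.39, 0.28 and -0.16 at day 13. At day 19 they were -0.42, 0.13, 1.12, 0.29 and -0.68, so among these clusters the sign turned only in cluster 0. Cluster 25, which was left unnamed and belongs to no named class, was led by Mepe, Chad, Bglap2 and Dkk1, and was singled out because its share of skeletal-lineage cells in the mutants lay above that in the controls. It held 8.46% (95% exact interval 7.70 to 9.27) of the mutant cells and 1.80% (1.45 to 2.22) of the control cells at day 13, and 6.91% (6.13 to 7.75) and 4.28% (3.23 to 5.55) at day 19, again with no test.

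Skeletal genes differed between genotypes in neutrophil-like cells, where Col1a1 rose and Col9a2 and Matn3 fell. Doublets of a blood cell and a skeletal cell are argued against by Col2a1, a cartilage collagen: at 2000 UMIs per cell, 98.8% and 79.5% of control and 93.3% and 79.7% of mutant neutrophil-like cells held a Col2a1 UMI at days 13 and 19, far above the 1.22% to 3.24% of cells marked as doublets. Free RNA from skeletal cells remains a candidate source. The bound used for it was 80% in every library, and the lowest value, 79.5% with an interval of 74.8 to 83.7, lies across it, so this test alone could not decide on free RNA. Blood cells do not make cartilage matrix, yet genes of that list also fell in B cell-like (14 of 20), erythroid-like (13 of 20) and monocyte- or macrophage-like cells (17 of 20). No biological explanation was tested.

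In chondrocyte-, B cell-, erythroid- and neutrophil-like cells alike, 16 genes shifted at least 2-fold in the same direction at both ages. Of these, 93.8% (15 of 16, among them Col1a1, Col3a1, Lum and Mmp13, higher, and Prelp, lower) had a level at least 5 times higher in one class than in the lowest. This is above the 80% set as the bound for free RNA from 1 cell class. The share among other genes at such levels was not computed. The test therefore cannot decide between free RNA and other causes. The other gene, BC023719 on chromosome 17, was higher in mutants. With that gene alone, 0% of such genes lay on chromosomes 7 and 11, which hold Acan and Sox9 (upper limit 97.5%). A segment carried along with either allele would not hold this gene, though 1 gene is too few to decide on such segments in general. The number of chromosomes could only be 1, so that test could not decide on strain background, which cannot be told apart from litter. The design has no group that would separate these from genotype.

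In the 5 chondrocyte-like clusters held by both genotypes, the Acan ratio lay below the median of the other cartilage matrix genes, although it was the lowest of them only in cluster 1 and at day 19 in cluster 4. Its log2 ratio minus the median of the 19 other list members was -1.09 and -1.27 in cluster 1 at days 13 and 19, and -0.16 and -0.43 in the superficial cluster 0. A loss of counts from the Acan allele that carries the recombinase would change Acan in every cell type by about -1 on the log2 scale. In pericyte-like cells the ratio was -0.19 and -0.17, and the interval over resampled cells ran from -0.576 to 0.240 at day 13 and from -0.764 to 0.585 at day 19. Both intervals lie above -1, with 1 library per group, which argues against a loss of that full size in pericyte-like cells. The bound that would argue against any such loss was a lower end above -0.5 at both ages, and it was not met. A smaller loss therefore cannot be told apart from a change in Acan expression by this test. The day 19 control held 25 pericyte-like cells, fewer than the 50 asked of class comparisons. Free Acan RNA adding to control cells was at most 14.9% of the difference in cluster 1, where 50% was needed. This argues against it as the main source of the Acan difference in cluster 1. The other clusters were not tested in this way, nor was the part of the Acan ratio beyond the other cartilage matrix genes. A dependence of Acan on Sox9 and unequal recombination between cells were not tested.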

How the results depend on the processing

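Chosen after the data were seen were the clustering without listed genes, the counts of genes with the superficial cluster alone or left out, with other resolutions or without cycling cells, and the count for age under each cell set. Leaving out 1 library leaves no residual degree of freedom, so no test was run that way. The count of genes that differ by genotype stayed within 1.5 times of 3983 except for DESeq2, with 2361, and the superficial cluster alone, with 722, which tested fewer genes (10490) in fewer cells. The cartilage matrix median stayed between -1.73 and -1.25 at day 13 and between -1.34 and -1.04 at day 19. Of the list medians recomputed under the alternatives, 499 stayed within their bootstrap interval, 69 moved beyond it and 4 reversed, counting as reversed only medians whose interval excluded 0. Where the interval reached across 0, 18 medians took the other sign under at least 1 alternative, 42 values in all, in the Wnt, hedgehog, p53, interferon, hypertrophy, glycolysis, endoplasmic reticulum, SOX, macrophage and osteoclast lists and, at day 19, the superficial-zone list. Of the ratios of named genes, 309 stayed within their counting interval, 329 moved beyond it and 0 reversed. Depth limits genes near 3 counts per library, and the 1051 control chondrocyte-like cells at day 19 give the shallowest sum.

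The count for age, 109, was 389 with RLE factors, 272 without the filter, 0 without genotype, 75 with doublets kept, 66 and 42 at 200 and 1000 genes, 195 and 80 at 5% and 25% mitochondrial UMIs, 165 with libraries clustered apart, 31 and 45 at resolutions 0.5 and 2.0, 215 without listed genes, 24 in skeletal-lineage cells, 314 without cycling cells, 258 in the superficial cluster and 249 without it. Sox9 at day 13 (-0.87) was -1.01 in skeletal-lineage cells, -0.69 by mean share, -1.13 with TMM, -0.81 with doublets kept, -1.05 and -0.81 at 200 and 1000 genes, -0.93 and -0.83 at 5% and 25%, and -0.81 without cycling cells. At day 19 (-1.39) it was -1.31 by mean share, -1.51 with TMM, -1.47 and -1.32 at 200 and 1000 genes and -1.34 without cycling cells. The osteoblast median at day 13 (1.06) was 2.73 at 200 genes, 1.96 at 5% and 2.51 with libraries apart, and at day 19 (1.16) 2.29 at 200 genes, with 0.15 at 1000 genes inside its wide interval. The fibroblast matrix median was 1.34 with TMM at day 13 and 1.28 in skeletal-lineage cells at day 19.

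The osteoblast-like share differed by 10.3 points at day 13 and 4.42 at day 19. With doublets kept these were 13.5 and 6.17, at 200 genes 1.88 and 1.60, at 1000 genes 12.2 and 6.35, at 5% 12.5 and 5.40, at 25% 12.4 and 5.99, at resolution 0.5 15.03 and 7.39, at 2.0 14.8 and 6.65, without listed genes 11.4 and 5.04, among skeletal-lineage cells 15.3 and 10.1, and with libraries apart 5.396 at day 13. Reversed in this sense were the neutrophil median at day 19 at 200 genes (-0.14), with libraries apart (-0.28) and without listed genes (-0.37), the macrophage median at day 13 with every member that had a count (0.23), and the chondrocyte-like share at day 19 among skeletal-lineage cells (-5.70 points). For results that moved, the cause was not tested.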

Other observations

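No test in this part was planned, and the values below were chosen after they were seen.

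Bglap and Bglap2 are neighbouring and near-identical osteocalcin genes. In osteoblast-like cells Bglap2 stood at 4020 CPM in the control and 35.4 in the mutant at day 13 and at 16493 and 42.5 at day 19, while Bglap stood at 7609 and 6380 at day 13 and at 35203 and 12457 at day 19. In cluster 25 Bglap2 stood at 838 and 25.8 CPM at day 13 and at 1588 and 15.7 at day 19. The osteoblast-like values of the controls rest on 29 and 16 cells, under the 50 asked of class comparisons. Reads can be shared between these copies and the strain is not given, so the levels are uncertain.

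Cartilage RNA was also found in neutrophil-like cells. Col2a1 stood there at 4566 and 1751 CPM at day 13 and at 4523 and 1431 at day 19 in control and mutant, and Acan at 240 and 76.6 and at 273 and 56.7. At 2000 UMIs per cell, a Bglap UMI was found in 16.9% of mutant chondrocyte-like cells at each age and in 9.23% and 8.39% of mutant neutrophil-like cells, at the depths given with Sox9. A Col1a1 UMI was found in 84.9% and 68.7% of mutant chondrocyte-like cells at days 13 and 19 and in 92.8% and 56.4% of mutant neutrophil-like cells.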
